A study of Mus musculus with 16 samples.

How the data were processed

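Circular chromosome conformation capture with sequencing (4C-seq) records which parts of the genome lie close to 1 chosen locus, the viewpoint. Per the labels' protocols, mouse embryonic fibroblasts prepared at embryonic day 13.5 and grown to passage 4 were crosslinked in 1% formaldehyde, the chromatin was cut with HindIII and ligated, and the product was cut again with NlaIII and circularised. Inverse PCR with primers at the viewpoint then amplified the ligated partners, with 3.2 µg of template split over 16 reactions, and the products were pooled for sequencing. The 16 libraries came from 2 viewpoints, 2 genotypes and 4 replicates per genotype. The replicates are 4 numbered pairs of a Rb1+/+ and a Rb1L/L culture, and the same pair identifiers appear at both viewpoints, so the 16 libraries were taken to come from 8 cultures. What the members of a pair share is not stated in the labels.

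Each library had 2 deposited files. The first lists restriction sites in BED format, mostly as intervals of 6 bp, each with a p-value or q-value that the authors deposited without a header. All of these values were below 0.05, neighbouring sites often had the same value, and which of the 2 quantities the column holds could not be settled. The second file lists the regions that the authors called significant, as deposited coordinates with no score. The regions of a library did not overlap, and each of its listed sites lay inside one of them. The genome build was mm9, per the submitters' processing notes. The aligner, the caller and its thresholds are not given in the sources used here. The deposited lists hold no read counts, so sequencing depth is unknown and a library's number of listed sites is its only measure of yield. A list that stops at a p-value threshold also moves with depth, because a deeper library can list more sites. The deposited p-values were used only to filter sites in an alternative setting.

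Sites and regions were summarised per library in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. A site on the viewpoint's own chromosome was counted as cis and any other as trans. Distances were measured from the middle of a stretch without listed sites taken to hold the viewpoint, chosen as described below. The stretches are 2.61 Mb (Pole) and 3.05 Mb (Cdca3) long. The planned share of cis sites within 1 Mb was therefore 0 in all 16 libraries by this placement. The share within 5 Mb, planned as an alternative, was made a result of its own after the values were seen. The position of a viewpoint is not marked in the files, and no mm9 gene annotation was used. The plan was to place it at the densest stretch of cis sites. With the near sites absent this was not possible, and a search for an empty stretch with dense flanks, tried instead, picked a stretch on chromosome 6 away from Cdca3. The viewpoint was therefore taken to lie in the stretch without listed sites of its own libraries into which the approximate promoter position fell, from general knowledge of the mouse genome. Longer empty stretches exist on the same chromosomes, 12 for Pole and 8 for Cdca3, so distances to the viewpoint carry this uncertainty. Gene names beside the viewpoints came from the gene order of the GRCm38.p6 RefSeq annotation, with none of its coordinates. Without mm9 gene coordinates, windows and regions are named by mm9 position, 1-based.

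Genotypes were compared within each viewpoint, 4 libraries against 4. Single values (sites, shares, numbers of regions) were compared by an exact two-sided permutation test over the 70 assignments, whose smallest p is 0.0286, and 95% intervals of the difference came from inverting that test. The viewpoint chromosome was divided into 500-kb windows. Windows with at least 8 sites over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (eBayes with a trend) on log2 of sites plus 0.5, per 1000 cis sites, with Benjamini-Hochberg adjustment. Fold changes are differences of mean log2 values on that scale. Where libraries list few sites they depend on the added 0.5 and can exceed the ratio of the mean site numbers. The count-based test planned for the case of deposited reads did not apply. The overlap of region lists was measured as base pairs covered in both libraries over base pairs covered in either, and the mean within genotypes minus the mean between genotypes was tested one-sided over the 35 splits into 4 and 4. Regions overlapping by at least 1 bp in any library were merged, and each merged region was compared by Fisher's exact test. The share of trans sites on each of 19 chromosomes was compared by the exact permutation test with Benjamini-Hochberg adjustment. The genotype effect was compared between viewpoints by an exact permutation test of the Pole value minus the Cdca3 value of each culture.

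The window test was tested on simulated data made from each viewpoint's own windows, with 20 windows changed. At Pole, over 167 windows, it recovered 12.2% of 2-fold, 38.4% of 4-fold and 65.6% of 16-fold changes. At Cdca3, over 161 windows, it recovered 28.7%, 46.4% and 63.3%. Mean false calls per run were 0.16 to 0.9 at Pole and 0.14 to 0.64 at Cdca3. The simulated noise was normal and independent between windows and libraries. The real libraries share structure, seen in the splits below, so these rates need not hold for them. No pair of libraries was a copy of another: sites listed in both libraries came to at most 21.6% of those listed in either, and to at most 40.7% of those of the smaller library. All intervals around the share of a single library are Wilson intervals and cover counting error only, since sites next to each other are not independent.

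The comparisons, tests, window size and alternatives were chosen before the data were examined, except where stated. The rule for naming was, per viewpoint and direction, the 5 windows with the smallest p among those past the adjusted threshold, or where fewer passed the 3 with the smallest p as values that did not pass. It also covered up to 5 of the longest merged regions present in all 8 libraries, and up to 5 per direction of those called in at least 3 libraries of one genotype and at most 1 of the other. The alternatives varied the windows, pseudocount, filter, denominator, distance, overlap definition, regions counted, thinning to equal numbers of sites, the MEF pair as a replicate block and each library left out in turn. Chosen after the data were seen were a stricter limit of 0.01 on the deposited p-value, leaving out MEF pair 1, counting sites under 20 bp apart once, a 10-Mb distance, other denominators and thinning for the 5-Mb share, and testing the windows called in all 8 libraries alone. Alternatives that need read counts or a score per region were not run.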

Results

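The data are 16 4C-seq libraries from mouse embryonic fibroblasts (MEFs), primary cells grown from embryos. They compare cells with an intact Rb1 gene (Rb1+/+) and cells homozygous for the Rb1L allele (Rb1L/L). Rb1 encodes pRb, a protein that restrains entry into the cell cycle, and from other work the L allele is known to alter the cleft through which pRb binds LXCXE-motif proteins. The viewpoints were a pair of bidirectional promoters, short stretches from which genes are read in opposite directions. The first lies between Pole, the catalytic subunit of DNA polymerase epsilon, and Pxmp2, a peroxisomal membrane protein. The second lies between Cdca3, a cell division protein, and Usp5, a deubiquitinating enzyme. The title of the series concerns condensin II, a chromosome-compacting complex, and its recruitment by pRb to promoters, so the comparison asks whether the contacts of these promoters differ in Rb1L/L cells. Each viewpoint had 4 libraries per genotype.

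The Pole/Pxmp2 promoter was taken to lie in a stretch of chromosome 5 in which its libraries listed no site, from 109110987 to 111716060 (mm9, 2.61 Mb long). In the gene order of a later mouse annotation, Pole and Pxmp2 are next to each other, with Pgam5, Ankle2, Golga3 and Chfr on one side and P2rx2, Lrcol1, Fbrsl1 and Galnt9 on the other. The Cdca3/Usp5 promoter was taken to lie in the stretch of chromosome 6 from 122734331 to 125781765 (3.05 Mb). Its neighbours are Tpi1, Spsb2, Lrrc23 and Eno2 on one side and Gnb3, P3h3, Gpr162 and Cd4 on the other. By the way the stretches were chosen, none of the 8 libraries of a viewpoint listed a site in its stretch. The lists therefore describe contacts outside these stretches. Where in its stretch a promoter lies is not known, so its distance to the nearest listed site is not known either. Contacts within the gene pairs or with their close neighbours were not measured here.

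The Cdca3/Usp5 viewpoint listed more sites than the Pole/Pxmp2 viewpoint. Pole libraries listed 12711 ± 4678 sites in Rb1+/+ cells and 13310 ± 4701 in Rb1L/L cells (SD, n = 4 each), and single libraries ran from 6485 to 17522. The difference of 599 sites was small against this spread (exact permutation p = 0.971, higher in 2 of 4 MEF pairs), and ran from -996 to 2874 when single libraries were left out. Cdca3 libraries listed 25692 ± 4606 sites in Rb1+/+ cells and 30284 ± 10796 in Rb1L/L cells (SD, n = 4 each), from 15802 to 39650. The difference of 4592 sites lay within the spread between libraries (exact permutation p = 0.457, higher in 2 of 4 pairs). It ran from 1470 without Rb1L/L replicate 2 to 9420 without Rb1L/L replicate 1. These numbers stand in for depth, which the lists do not give.

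**Figure D1:**
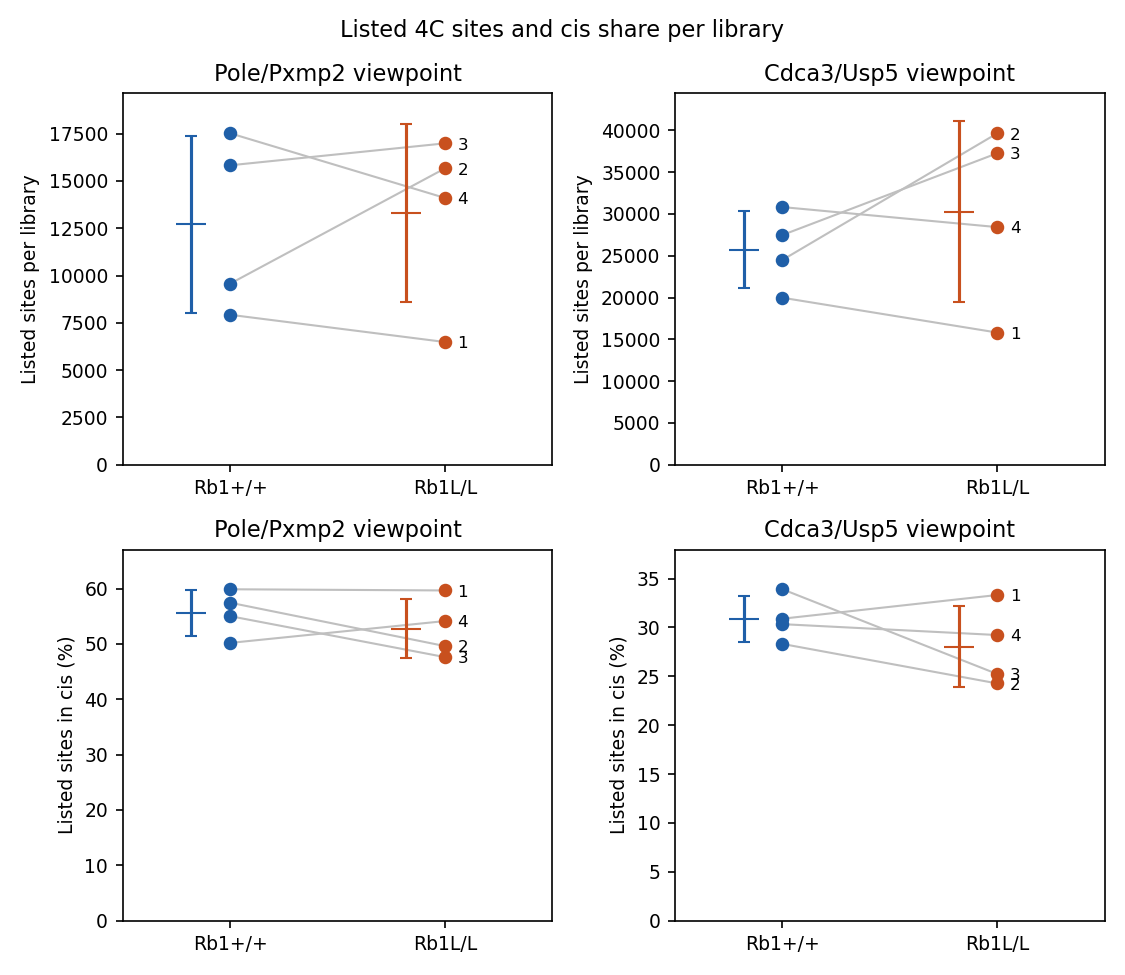
Number of listed 4C sites (top) and percent of listed sites on the viewpoint chromosome (bottom) per library, for the Pole/Pxmp2 (left) and Cdca3/Usp5 (right) viewpoints. Points are libraries, grey lines join the libraries of a MEF pair (numbers 1 to 4), and bars show mean ± SD of 4 libraries; the genotypes overlap in all 4 panels, as in the Pole cis share of 55.6% against 52.8%.

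At both promoters the mean share of contacts on the viewpoint's own chromosome was slightly lower in Rb1L/L cells, by less than the SD of the Rb1L/L libraries. At Cdca3 the difference exceeded the SD of the Rb1+/+ libraries. At Pole, 55.6% ± 4.14 of the sites were in cis in Rb1+/+ cells and 52.8% ± 5.35 in Rb1L/L cells (SD, n = 4 each). The difference was -2.87 percentage points (exact permutation p = 0.371, lower in 3 of 4 pairs), with a 95% interval from -12.3 to 9.44. It ran from -5.18 without Rb1L/L replicate 1 to -1.16 without Rb1L/L replicate 3, and was -1.21 over sites with a deposited p-value or q-value under 0.01. At Cdca3 the cis share was 30.9% ± 2.31 in Rb1+/+ cells and 28.0% ± 4.14 in Rb1L/L cells (SD, n = 4 each). The difference was -2.85 points (exact permutation p = 0.257, lower in 3 of 4 pairs), with a 95% interval from -9.60 to 5.00. It ran from -4.62 without Rb1L/L replicate 1 to -1.60 without Rb1L/L replicate 2, was -4.61 without MEF pair 1, and was -0.564 over sites with a deposited value under 0.01. At either viewpoint the genotype difference cannot be separated from the number of listed sites. Cis share fell with site number (Pearson r = -0.893 at Pole, -0.749 at Cdca3, 8 libraries each). In pairs 2 and 3, Rb1L/L listed more sites and had the lower share at both. In pairs 1 and 4 it listed fewer. Its Pole share there was 59.7% against 59.9% and 54.1% against 50.2%. At Cdca3 it was 33.3% against 30.9% and 29.2% against 30.3%. The genotype difference itself did not differ detectably between the viewpoints (-0.0234 points, exact permutation p = 1), and this value changed sign, from -1.72 to 1.23, when single pairs were left out.

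The distance bins below differ in width, and no site is listed in the stretch taken to hold a promoter. Shares per bin are therefore not densities of contacts. Along chromosome 5, most listed cis sites of the Pole viewpoint lay 10 to 50 Mb away, in a bin much wider than the nearer ones. That bin held 58.8% ± 1.82 of cis sites in Rb1+/+ and 59.4% ± 1.09 in Rb1L/L cells, and 19.6% ± 2.42 and 19.3% ± 4.06 lay beyond 50 Mb (SD, n = 4 each). Within 5 Mb lay 13.53% ± 1.68 and 12.3% ± 2.01, a difference of -1.20 points (exact permutation p = 0.4, 95% interval -5.02 to 2.94). It ran from -2.14 without Rb1L/L replicate 1 to -0.463 without Rb1+/+ replicate 1, and was -0.285 within 10 Mb. The centromeric side of the promoter held 65.2% ± 2.44 and 65.6% ± 3.72 of cis sites. Along chromosome 6, the 10 to 50 Mb bin of the Cdca3 promoter held 45.6% ± 0.980 of cis sites in Rb1+/+ and 46.4% ± 1.30 in Rb1L/L cells, and 33.8% ± 0.376 and 34.4% ± 3.62 lay beyond 50 Mb. Within 5 Mb lay 15.3% ± 1.79 and 15.0% ± 3.06, a difference of -0.283 points (exact permutation p = 0.83, 95% interval -4.41 to 5.73). It ran from -1.80 without Rb1L/L replicate 1 to 0.441 without Rb1+/+ replicate 1, and was -1.44 within 10 Mb, so which promoter had the larger difference turned with the distance. The centromeric side held 74.1% ± 0.559 and 73.7% ± 2.55. At neither promoter were these shares set against the length of each side, so no preference for a side can be read from them. The genotype difference in the 5-Mb share did not differ detectably between viewpoints (-0.919 points, exact permutation p = 0.143, from -1.29 to -0.331 when single pairs were left out). Called regions covered 40.3% ± 6.25 of chromosome 5 in Rb1+/+ and 40.1% ± 6.69 in Rb1L/L cells at Pole, and 38.8% ± 4.26 and 39.4% ± 5.86 of chromosome 6 at Cdca3.

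**Figure D2:**
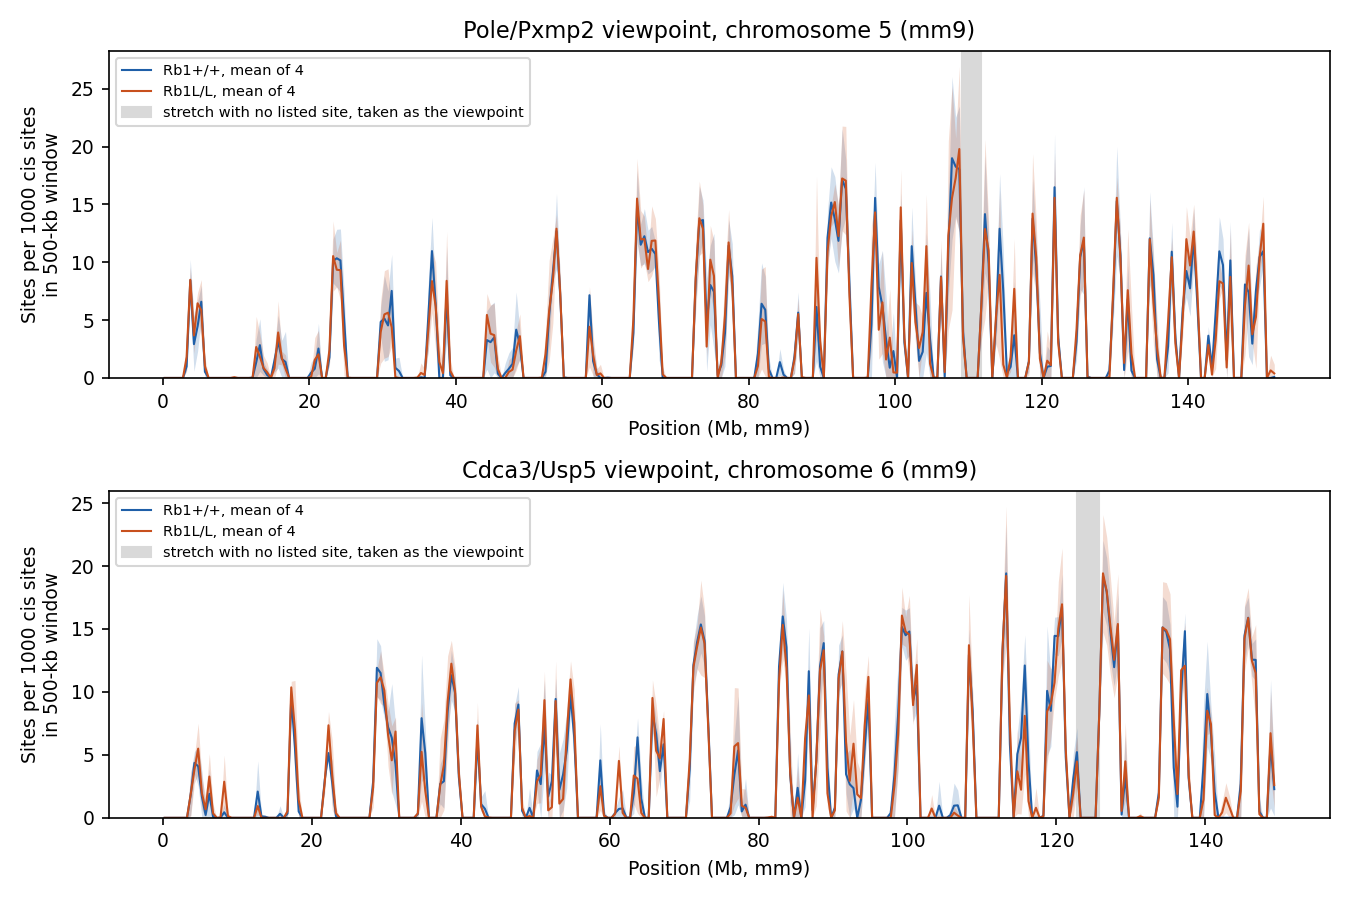
Listed sites per 1000 cis sites in 500-kb windows along chromosome 5 for the Pole/Pxmp2 viewpoint (top) and chromosome 6 for the Cdca3/Usp5 viewpoint (bottom), position in Mb (mm9). Lines are means of 4 libraries per genotype, shading is ± SD, and the grey band is the stretch without listed sites taken as the viewpoint; the genotype means largely overlie each other, and 0 of 167 and 0 of 161 windows passed the test.

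No stretch of either chromosome passed the test for a difference between genotypes. On chromosome 5, limma called 0 of 167 windows after adjustment (smallest adjusted p = 0.983), and 2 windows had an unadjusted p under 0.05, both lower in Rb1L/L. On chromosome 6 it called 0 of 161 windows (smallest adjusted p = 0.955), and 4 had an unadjusted p under 0.05, 3 of them higher in Rb1L/L. No other tool was run on the windows. The precision was better in windows that overlapped a called region in all 8 libraries. That set leaves out any window called in 1 genotype only, so intervals close to no change are partly fixed by this choice. The largest absolute log2 fold change in the set was 3.00 on chromosome 5 and 2.66 on chromosome 6. The 108 windows of chromosome 5 that overlapped a called region in all 8 libraries held 87.2% of cis sites, and their median 95% interval was ± 0.81 on the log2 scale. For 50 of them the interval lay within 1 log2 unit of no change. On chromosome 6 there were 106 such windows with 89.9% of cis sites, a median interval of ± 0.59, and 61 windows within 1 log2 unit. Over all tested windows the median interval was ± 2.11 and ± 1.72, so that a change of a few fold in a sparse window was not detectable.

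The windows closest to the threshold are given as values that did not pass. On chromosome 5, the window from 114.5 to 115.0 Mb held 7.50 ± 3.54 sites per 1000 cis sites in Rb1+/+ and 1.16 ± 1.36 in Rb1L/L libraries (SD, n = 4 each), a log2 fold change of -4.14 ± 1.45 (SE) by limma. The window from 97.5 to 98.0 Mb had a log2 fold change of -1.21, and that from 84.0 to 84.5 Mb held sites in 3 of 4 Rb1+/+ and 0 of 4 Rb1L/L libraries. In the other direction, the window from 89.5 to 90 Mb had a log2 fold change of 2.80. The window from 116.0 to 116.5 Mb held 3.69 ± 4.65 and 7.71 ± 4.34 sites per 1000 in Rb1+/+ and Rb1L/L libraries, with a log2 fold change of 3.00 that rests on libraries with few sites, and that from 37.5 to 38.0 Mb held sites in 0 of 4 Rb1+/+ and 2 of 4 Rb1L/L libraries. On chromosome 6, the window from 119.5 to 120.0 Mb, the nearest of these to the Cdca3 promoter, held 14.5 ± 1.48 sites per 1000 in Rb1+/+ and 10.8 ± 1.38 in Rb1L/L libraries (SD, n = 4 each), a log2 fold change of -0.43 ± 0.15 (SE). The windows from 115.5 to 116.0 Mb and from 115.0 to 115.5 Mb had log2 fold changes of -0.73 and -2.25. In the other direction, the window from 61.0 to 61.5 Mb held 0.707 ± 0.881 and 4.52 ± 1.21 sites per 1000, a log2 fold change of 3.86 ± 1.46 (SE). The windows from 142.5 to 143.0 Mb and from 143.0 to 143.5 Mb each held sites in 0 of 4 Rb1+/+ and 3 of 4 Rb1L/L libraries.

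The numbers of significant regions were close in the genotypes. Pole libraries had 219 ± 44.5 regions in Rb1+/+ and 224 ± 54.0 in Rb1L/L cells (SD, n = 4 each, difference 4.75, exact permutation p = 0.943, 95% interval -122 to 81.6). The difference ran from -10.9 without Rb1+/+ replicate 1 to 31.7 without Rb1L/L replicate 1. They covered 292 to 794 Mb per library. Cdca3 libraries had 243 ± 16.3 and 256 ± 13.1 regions (SD, n = 4 each, difference 13, exact permutation p = 0.286, 95% interval -22.9 to 45.9), which covered 676 to 1031 Mb. The difference ran from 7.33 without Rb1L/L replicate 2 to 20 without Rb1+/+ replicate 3.

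Libraries of one genotype did not share detectably more of their regions than libraries of different genotypes. At Pole the overlap was 38.5% ± 12.8 over the 12 pairs of libraries within a genotype and 39.3% ± 13.51 over the 16 pairs between genotypes (SD over pairs, which share libraries). The difference was -0.731 points (exact one-sided permutation p = 0.571), and ran from -2.19 to 0.590, the latter without Rb1+/+ replicate 4, when single libraries were left out. At Cdca3 it was 65.0% ± 9.07 within and 64.9% ± 9.23 between, a difference of 0.0410 points (exact one-sided permutation p = 0.429). It ran from -0.861 without Rb1+/+ replicate 1 to 0.719 without Rb1L/L replicate 3, and was -0.859 on chromosome 6 alone. The overlap of the 28 library pairs was 74.6% ± 6.86 on chromosome 5 and 35.7% ± 13.8 on the other chromosomes at Pole, and 76.0% ± 5.31 on chromosome 6 and 64.2% ± 9.27 elsewhere at Cdca3. Unequal covered lengths limit this overlap. At Pole, every pair with Rb1L/L replicate 1, which covered 292 Mb, lay between 21.1% and 23.7%. That held for Rb1+/+ replicate 1, which covered 360 Mb (22.5%), as for Rb1+/+ replicate 4, which covered 794 Mb (23.7%). Unequal length alone therefore does not account for these low values. Whether the means depend on library size was not tested. The pairs between genotypes include same-numbered pairs, whose mean overlap was 43.0% at Pole and 68.0% at Cdca3.

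**Figure D3:**
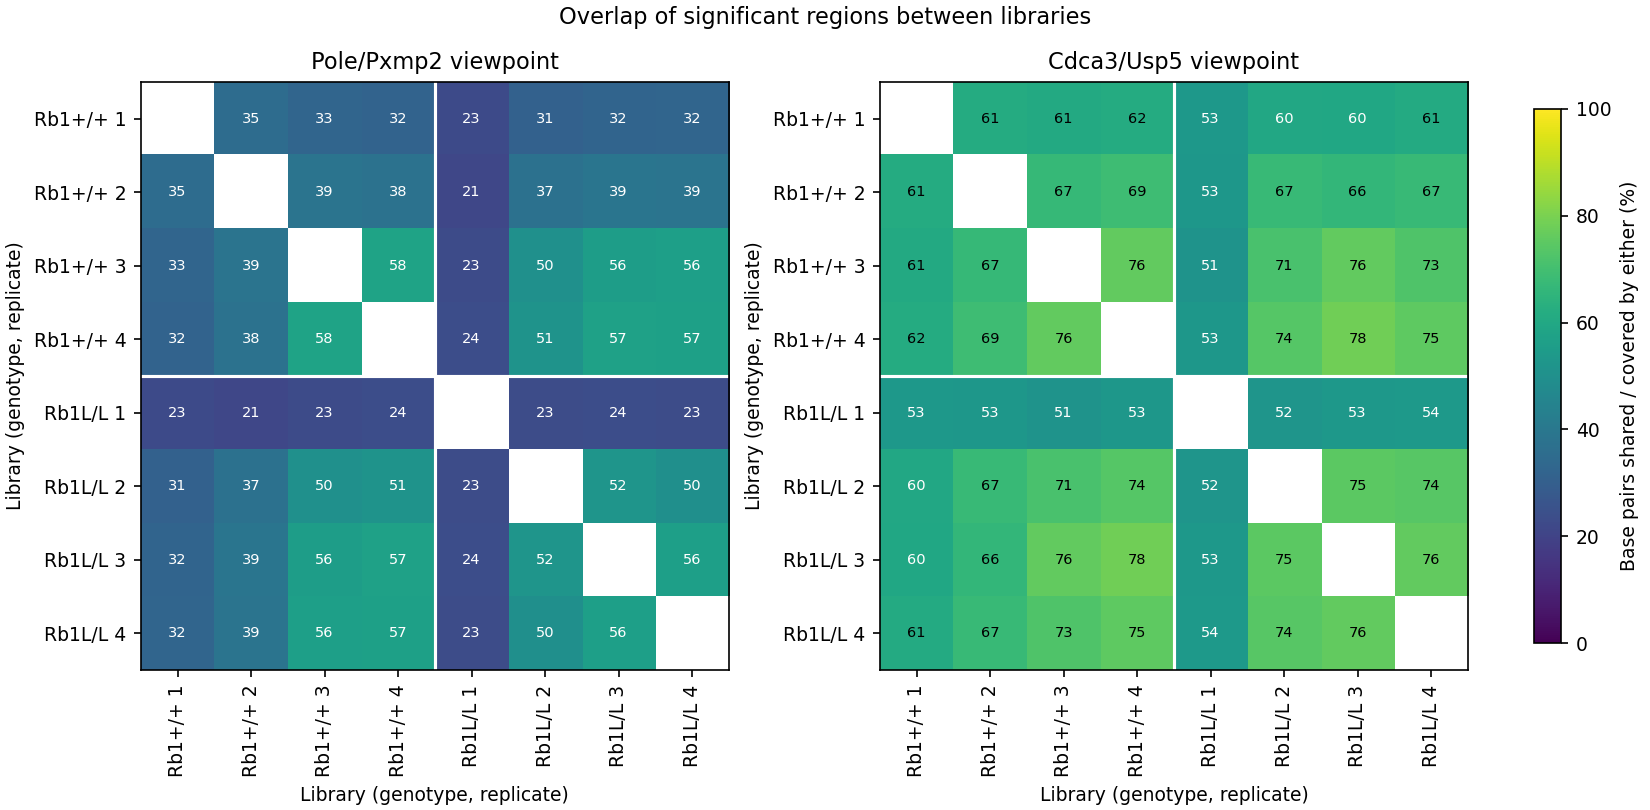
Overlap of the significant regions of each pair of libraries, as base pairs shared over base pairs covered by either, in percent, for the Pole/Pxmp2 (left) and Cdca3/Usp5 (right) viewpoints. White lines part the genotypes; the overlap runs from 21.1% to 58.1% at Pole and from 51.2% to 78.5% at Cdca3, and the mean within genotypes (38.5% and 65.0%) is close to that between genotypes (39.3% and 64.9%).

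Many long trans regions were called in both genotypes. The Pole lists merged into 326 regions, 50 on chromosome 5, of which 36 were called in all 8 libraries, and 276 elsewhere, of which 29 were called in all 8. The longest of those in all 8 lay on chromosome 9 from 52337826 to 73924713 (21.6 Mb), chromosome 4 from 122113189 to 142547762 (20.4 Mb), chromosome 14 from 54056837 to 71742834, chromosome 15 from 72241699 to 86903802 and chromosome 17 from 22915472 to 36913387. The Cdca3 lists merged into 292 regions, 52 on chromosome 6 with 29 in all 8 libraries, and 240 elsewhere with 91 in all 8. The longest lay on chromosome 9 from 52380820 to 73839012 (21.5 Mb), chromosome 4 from 121799197 to 142774657 (21.0 Mb), chromosome 12 from 69066283 to 89214079, chromosome 13 from 41538420 to 60788863 and chromosome 14 from 53848969 to 72121326. A merged region joins overlapping calls and is longer than what each library called: base pairs called in all 8 libraries came to 74.0 Mb at Pole and 405 Mb at Cdca3.

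Of the merged regions, 10 of 326 at Pole and 14 of 292 at Cdca3 were called in at least 3 libraries of one genotype and at most 1 of the other. Over the other splits of the 8 libraries into 4 and 4, the mean number was 18.1 at Pole and 14.8 at Cdca3. Neither real number exceeded this mean, so the regions named below are not evidence of a genotype difference. With 4 libraries against 4, Fisher's exact p cannot go below 0.0286, and at least 187 of 326 regions at Pole or 167 of 292 at Cdca3 would have to reach it for any to pass adjustment, so the adjusted test could not single out a few regions. The number of regions leaning to a genotype was 31 without Rb1+/+ replicate 3 and 30 without Rb1+/+ replicate 4 at Pole. It was 24 without Rb1+/+ replicate 3 and 9 without Rb1L/L replicate 4 at Cdca3. The limits of at least 3 and at most 1 stayed fixed while 1 genotype had 3 libraries left. These numbers are therefore not directly comparable with 10 and 14. At Pole, 2 regions were called in at least 3 Rb1+/+ and at most 1 Rb1L/L libraries, on chromosome 17 from 54966385 to 58149787 and chromosome 5 from 84165020 to 84747462. The opposite held for 8 regions. Among them were chromosome 14 from 98111509 to 103231814 and chromosome 15 from 9811033 to 12993141, each in 1 of 4 Rb1+/+ and 4 of 4 Rb1L/L libraries, and X from 47790721 to 51308599 and chromosome 1 from 50754486 to 53054070, each in 0 of 4 and 3 of 4. A further one was chromosome 10 from 91975661 to 98544154 (1 of 4 and 3 of 4). Fisher's exact test passed 0 of the 326 regions after adjustment (smallest adjusted p = 1), and 0 had an unadjusted p under 0.05. At Cdca3, 4 regions leaned to Rb1+/+: chromosome 12 from 3008674 to 6201831 (4 of 4 and 1 of 4), chromosome 7 from 24574234 to 27201815 (3 of 4 and 0 of 4), chromosome 7 from 15681128 to 21538582 and chromosome 5 from 100761277 to 105291820. Of the 10 that leaned to Rb1L/L, the region on X from 80819398 to 83461377 was called in 0 of 4 Rb1+/+ and 4 of 4 Rb1L/L libraries (Fisher's exact p = 0.0286, adjusted p = 1). The others named by the rule were chromosome 18 from 9590083 to 14370448, X from 89593754 to 93400130, X from 53441523 to 55692056 and chromosome 4 from 31802133 to 33855321. Fisher's exact test passed 0 of the 292 regions after adjustment, and 1 had an unadjusted p under 0.05.

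The trans contacts were spread over 19 chromosomes at each viewpoint. At Pole, chromosome 7 held the largest share of trans sites, 9.57% ± 1.53 over the 8 libraries of both genotypes. The exact permutation test called 0 of 19 chromosomes after adjustment, and 0 had an unadjusted p under 0.05 (smallest adjusted p = 0.814). The nearest was chromosome 16, with 3.85% ± 0.357 in Rb1+/+ and 3.04% ± 0.521 in Rb1L/L libraries (SD, n = 4 each, exact permutation p = 0.0571, lower in 4 of 4 pairs). At Cdca3, 3 chromosomes reached the smallest p that the 70 assignments can give, and 0 passed after adjustment. Chromosome 2 held 9.06% ± 0.508 of trans sites in Rb1+/+ and 8.01% ± 0.408 in Rb1L/L libraries, and chromosome 11 held 7.99% ± 0.263 and 6.39% ± 1.30 (SD, n = 4 each), both lower in 4 of 4 pairs. X held 2.48% ± 0.754 in Rb1+/+ and 3.95% ± 0.598 in Rb1L/L libraries (SD, n = 4 each), higher in 4 of 4 pairs. For each of the 3 the exact permutation p was 0.0286 and the adjusted p 0.181. An adjusted p under 0.05 would need at least 11 of the 19 chromosomes at this smallest p, so a change on a few chromosomes could not pass.

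**Figure D4:**
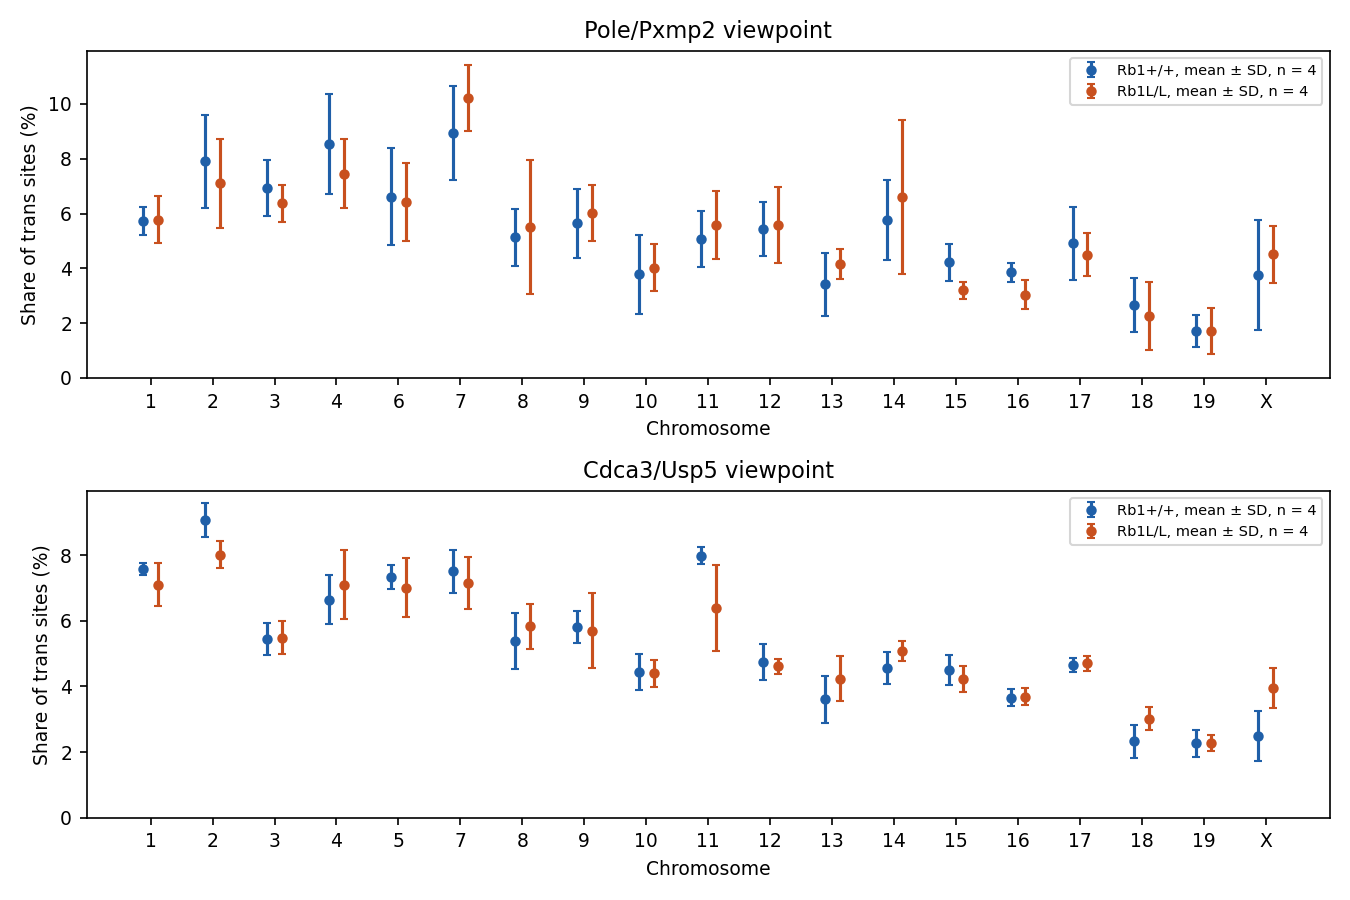
Percent of trans sites on each chromosome for the Pole/Pxmp2 (top) and Cdca3/Usp5 (bottom) viewpoints. Points are means of 4 libraries and bars are SD; at Cdca3 the genotypes stand apart on chromosomes 2 (9.06% and 8.01%), 11 (7.99% and 6.39%) and X (2.48% and 3.95%), with an exact permutation p of 0.0286 each and an adjusted p of 0.181.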

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

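None of the checks for a library far from the others of its group was chosen after the result was seen. The check covered 24 groups of 4 libraries, of which chance marks about 1 in 20. It marked 3 values, all from replicate 1 of Rb1L/L. The Pole library of that replicate had 143 significant regions, the lowest of its group. Its Cdca3 library had 19.5% of cis sites within 5 Mb, the highest of its group (95% Wilson interval 18.5% to 20.6%, counting error only). The same Cdca3 library covered 676 Mb, the lowest of its group. No cause was tested for these 3 values.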

How the results depend on the processing

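Chosen after the data were seen were the stricter limit of 0.01, leaving out MEF pair 1, counting close sites once, testing only windows called in all 8 libraries, and the 5-Mb share as a result of its own with its 10-Mb distance, denominator and thinning. Over 22 results, 298 alternative values were computed: 262 kept their direction or size, 25 changed sign, 11 moved, and 0 passed a threshold. That says little about stability: 26 had no test, and 66 could not pass, being paired tests of 4 pairs (smallest p 0.125), 3 libraries against 3 (0.1) or a 1-Mb share of 0. Adjusted tests of regions and chromosomes could pass only if most of them changed. Some values could not differ from the main one: leaving out sites within 20 kb removed none, and paired tests of single values repeat the main difference. Random thinning leaves the expected share unchanged, so it is no control for depth. The changes of sign were all in differences that were not called. The Pole difference in sites became -286 with sites under 0.01 and ran from -996 to 2874 when each library was left out. When each library was left out, the Pole difference in regions ran from -10.9 to 31.7 and the Cdca3 5-Mb difference from -1.80 to 0.441. Within-genotype minus between-genotype overlap ran from -2.19 to 0.590 at Pole and from -0.861 to 0.719 at Cdca3, where it was -0.859 on the viewpoint chromosome alone and -0.199 with regions holding a site under 0.01. At Pole that last setting gave -2.40, against -0.731 over all regions. The genotype difference in cis share at Pole minus that at Cdca3 ran from -1.72 to 1.23. The planned 1-Mb share, 0 everywhere by the placement of the viewpoints, became -1.20 (Pole) and -0.283 (Cdca3) as a difference within 5 Mb. Regions leaning to a genotype (10 at Pole, 14 at Cdca3) numbered 1 and 1 on the viewpoint chromosome, where fewer regions were counted, 215 and 178 as 500-kb windows, where long regions count many times, and 16 at Pole when at least 50% of the region had to be covered. When each library was left out they numbered 11 to 31 at Pole (31 without Rb1+/+ replicate 3, 30 without Rb1+/+ replicate 4) and 9 to 24 at Cdca3 (24 without Rb1+/+ replicate 3, 9 without Rb1L/L replicate 4). The limits of at least 3 and at most 1 were then applied to 3 libraries of 1 genotype. These numbers are therefore not directly comparable with 10 and 14. Otherwise the cause of the shifts was not tested. With the MEF pair as a replicate block, limma called 0 windows at Pole and 0 at Cdca3, with 5 and 9 windows at an unadjusted p under 0.05 against 2 and 4 without it. It changed no other call, but for single values the paired tests cannot go below 0.125. Same-numbered libraries deviated together for some pairs only (r from -0.103 to 0.278 at Pole and from -0.105 to 0.291 at Cdca3), and not every library correlated best with its own number. Leaving out windows within 1 Mb of the viewpoint removed 1 window at Pole and none at Cdca3, so it says nothing about the latter. Read minimums, shares of reads, count-based tests and a stricter region score were not run, since the lists give neither reads nor scores, and depth stays unknown.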

Other observations

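Chosen after the result was seen were the tests of cis share against number of sites, of site numbers and cis shares between viewpoints, and of the window splits, as well as the choice of the X chromosome for a closer look. Nearly all trans base pairs called in most Pole libraries were also called in most Cdca3 libraries, whose set was much larger. Regions called in single libraries were not compared in this way. On chromosomes other than 5 and 6, base pairs called in at least 6 of 8 libraries came to 262 Mb at Pole and 647 Mb at Cdca3, and 260 Mb were in both, 99.3% of the Pole set and 40.2% of the Cdca3 set. Base pairs called in all 16 libraries formed 25 segments with 33.8 Mb in total. The longest was on chromosome 7 from 132349572 to 136128047 (3.78 Mb). Some libraries of each promoter had regions in the neighbourhood of the other. Cdca3 libraries had regions in the empty stretch around Pole in 4 of 4 Rb1+/+ libraries, covering 78.3% ± 20.01 of it, and 4 of 4 Rb1L/L libraries, covering 58.7% ± 19.1, against 36.7% and 37.6% of chromosome 5 as a whole (SD, n = 4 each, difference -19.6 points, exact permutation p = 0.257). In Rb1L/L replicate 1 of these, no site was listed there and coverage was 30.3% against 30.9% of the chromosome. Pole libraries had regions in the stretch around Cdca3 in 3 of 4 Rb1+/+ and 2 of 4 Rb1L/L libraries, covering 36.2% ± 31.4 and 28.8% ± 33.2 of it against 24.1% and 24.9% of chromosome 6 (SD, n = 4 each), and 5 of 8 listed no site there. Neither stretch was tested against other stretches of its chromosome, so no preference can be read from these values.

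The overlap of the trans regions of both promoters is the first pattern weighed. It was 3.17 times the mean of 1000 circular shifts of the regions (82.0 Mb, highest 132 Mb; permutation p = 0.001, the smallest these shifts can give), which argues against chance placement of long regions. Many reads of one viewpoint counted in the other library would put the other viewpoint's chromosome first in sites per Mb. Its median rank was 7 in Pole and 6 in Cdca3 libraries, so 6 is the lower of these. That argues only against a leak large enough to bring a whole chromosome first. A smaller leak, or one concentrated at the other viewpoint, cannot be excluded by this rank. The coverage of the other viewpoint's stretch, given above, was not tested for this. The overlap was also high when the sets came from different genotypes, and so from different cultures: 97.1% of the Pole Rb1+/+ set lay in the Cdca3 Rb1L/L set. A shared compartment of gene-rich chromatin may be the source, but uneven density of restriction sites or of mappable sequence was not tested and stays open.

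The second pattern is the larger X share at Cdca3 in Rb1L/L cells, which did not pass adjustment. If the number of X chromosomes per culture were the cause, the X shares of a culture would go together at both viewpoints. Over the 8 cultures they gave Pearson r = 0.567 (permutation p = 0.140, adjusted 0.175 over 10 relations, 0.744 without the 2 farthest cultures) and Spearman rho = 0.452 (permutation p = 0.267), which cannot decide, and the sex of the embryos is not in the labels used here. The number of sites is open too: Pearson r = -0.0794 (permutation p = 0.85, adjusted 0.85) and Spearman rho = 0.0952 (permutation p = 0.840) lie in the range set beforehand as evidence against it, but r ran from -0.363 to 0.566 when each library was left out, wider than that range (a check made once r was known), and was 0.331 without the 2 farthest libraries. At Cdca3, X was higher in Rb1L/L by 1.5 and 0.419 points in the 2 pairs in which Rb1L/L listed fewer sites. At Pole the X share was 3.74% ± 2.01 in Rb1+/+ and 4.51% ± 1.04 in Rb1L/L libraries (SD, n = 4 each, exact permutation p = 0.571). It was higher in Rb1L/L in 3 of 4 pairs there, but in pair 1 it was 6.57% in Rb1+/+ and 3.71% in Rb1L/L. Genotype, X number, number of sites and chance may each underlie the difference at Cdca3.

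The third pattern is that libraries with more sites had a lower cis share. The number of sites is also the denominator of that share, so part of the relation may be built in. The permutation tests of it do not allow for this. Pearson r was -0.893 at Pole (permutation p = 0.00392, adjusted 0.0131 over 10 relations; -0.789 without the 2 farthest libraries; Spearman rho = -0.810, permutation p = 0.0218, adjusted 0.0931) and -0.749 at Cdca3 (permutation p = 0.0313, adjusted 0.0782; -0.502 without the 2 farthest; Spearman rho = -0.714, permutation p = 0.0576), so at Cdca3 it rests in part on those libraries. The numbers of sites of a culture went together at both viewpoints with genotype means removed (Pearson r = 0.924, permutation p = 0.000893, adjusted 0.00471; 0.684 without the 2 farthest; Spearman rho = 0.833, permutation p = 0.0154, adjusted 0.0931), which is consistent with a property of the culture or its ligated template and argues against genotype, since r was 0.914 before the means were removed. For the cis shares this stays open (Pearson r = 0.633, permutation p = 0.0948, adjusted 0.158; 0.442 without the 2 farthest; Spearman rho = 0.571, permutation p = 0.151). The genotype difference in cis share was not adjusted for the number of sites, so genotype and number of sites are not separated there. Read depth and shared library preparation are not in these lists and stay open.

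Over the 35 splits of the 8 libraries into 4 and 4, the windows past the adjusted threshold decide nothing, since the real split gave 0 at both viewpoints and all 35 and 35 splits give at least that; the highest other split gave 1 at Pole and 8 at Cdca3. At an unadjusted p under 0.05, the real split gave 2 windows at Pole and 4 at Cdca3, 30 and 18 of the 35 splits gave as many, and the highest other splits gave 36 and 45. For regions leaning to a genotype chance could not be excluded: the real split gave 10 at Pole and the highest other 34 (35 of 35 gave as many), and 14 at Cdca3 and the highest other 27 (21 of 35). Splits with several times the real count point to a structure of the samples, whose source was not tested. At Pole the highest split, for windows and for regions, set replicates 1 and 2 of both genotypes apart, among them the 3 libraries with the fewest sites (6485, 7925 and 9569). At Cdca3 the highest split for windows set apart Rb1+/+ replicates 1 and 2 and Rb1L/L replicates 1 and 4, and that for regions Rb1+/+ replicates 1, 2 and 4 and Rb1L/L replicate 1.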
